A study of Mus musculus with 8 samples.

How the data were processed

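RNA from C2C12 myotubes on day 4 of differentiation was labelled with Cy3 (500 ng per sample, per the labels' protocols) and hybridised to 1-colour Agilent arrays, 4 with control siRNA and 4 with macroH2A1.1 siRNA. A characteristic of the treated samples calls them a knockout, while titles and design name an siRNA, and the siRNA was followed. The labels call the replicates biological but do not say how cultures were made, so p-values measure the spread between these samples. The spot intensity values were extracted by the authors with Agilent Feature Extraction 10.7.3.1, per the file headers, which name genome build mm9. The processed intensity used here is background-subtracted by that software, per the file headers. The authors' series values are on a log2 scale, which the deposited table does not state: each column followed the log2 median signal of its own array (r between 0.9977 and 0.9996). Every column had the same median (6.29), 75th percentile (8.21) and range (5.65 to 17.98), as quantile normalization gives, and its background handling stays unknown. These values served as an alternative only.

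Log2 processed intensity was centred on each array's 75th percentile. Control spots were left out, spots flagged as outliers (143 to 236 per array) were set missing, and spots of 1 probe were averaged. Of 55681 probes, 33137 had a gene symbol: 27509 matched by accession to the RefSeq gene table (GRCm38.p6, used for names only), 3510 by current symbol, 396 by older symbol, and 1722 kept the name in the file. Another 22544 had none. Probes well above background on all 4 arrays of at least 1 group were kept (24988), and each gene was represented by its kept probe of highest mean, which gave 13798 genes. Several kept probes existed for 3891 genes. Where a gene was not well above background on any array of a group, the fold is a lower bound: the mean of the brighter group against, per dim array, the higher of its own signal and the lowest signal well above background. No column of another series was used (0 such columns).

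Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes, threshold 0.05) with no covariate. Gene lists (27) and cell type marker lists (9) were tested with camera at a preset correlation of 0.01, adjusted within each family, and again with an estimated correlation and with fry. Groups, the main test, lists, the naming rule and most alternatives were fixed before the data were examined. The naming rule takes a fixed set of genes (the macroH2A genes and anchors of myogenesis, mitochondria and NAD+ metabolism), the 15 largest changes per direction past the threshold with non-overlapping groups, and from each list up to 4 genes past the threshold or up to 2 that did not pass. It was written for the comparison without pairing. Its use on the paired fit was chosen after seeing the data, and the text names most but not every gene it takes.

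Whether replicate numbers pair the samples was decided by a rule set in advance, that samples of the same number correlate above 0.1 in every pair. The correlations and the counts of calls with the block were first seen together, so the check was not made blind to the calls. Deviations from the group mean correlated between samples of the same number at 0.61, 0.55, 0.66 and 0.41. The numbers therefore pair the samples by that rule. Every sample also matched its own number best, and the highest correlation with another number was -0.036. That adds little, since deviations sum to 0 within a group, which pushes correlations with other numbers below 0. Arrays of the same number also sit side by side on the slide, so a shared culture and a shared place cannot be told apart. All arrays share 1 slide and 1 scan, each of the 4 array columns holds 1 group, and both groups lie in each of the 2 rows.

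The scripts were tested on simulated data for this comparison (13745 genes, of which 67, 67 and 66 were changed by 1.5-fold, 2-fold and 4-fold). At these sizes, 44.8%, 77.6% and 87.9% of changed genes were recovered without pairing, with 2 unchanged genes among 142 called. With pairing 64.2%, 83.6% and 97% were recovered, with 14 unchanged genes among 177 called, more than the threshold allows on average. The simulation gave each gene independent noise and every pair the same change, so these shares need not hold for the real arrays. There Myh2, higher by 2.19 (log2), had limma adjusted p = 0.243 without pairing. Alternatives tried were normexp (offset 50), quantile normalization, median centring, the authors' series values, no filter and a stricter filter, the mean of a gene's probes, each probe alone, the replicate block, the array row as a block, the array column as a random block, trended robust eBayes, array weights, and leaving out each array. Settings of the paired fit, including leaving out each pair, were added after seeing the data. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.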

Results

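Gene expression was measured in C2C12 cells, a mouse myoblast line that fuses into contractile myotubes when serum is withdrawn. The cells had been transfected with a control siRNA or with an siRNA against macroH2A1.1, and RNA was taken on day 4 of differentiation. MacroH2A1.1 is a splice form of the histone variant macroH2A1 whose macrodomain binds ADP-ribose, a product of NAD+ consumption. The series title names mitochondrial respiration and nuclear NAD+ consumption, so the comparison asks which genes differ when this form is depleted. Each group held 4 samples, hybridised singly to 1-colour arrays on 1 slide. Between 46.9% and 49.8% of the 59305 non-control spots were well above background on each array, and no spot was saturated. Pairwise correlations between arrays lay between 0.9637 and 0.9918. The number of arrays limits the precision of every value below.

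The Macroh2a1 probes were lower in all 4 macroH2A1.1 siRNA samples than in any control sample. A probe taken as specific to the macroH2A1.1 form, from the transcripts listed for it and the peptide it encodes, read 1.03 ± 0.16 (SD, n = 4, log2 signal relative to the array's 75th percentile) in control cells and -0.39 ± 0.55 (SD, n = 4) in macroH2A1.1 siRNA cells, which left 37.4% of the control signal. Its sequence is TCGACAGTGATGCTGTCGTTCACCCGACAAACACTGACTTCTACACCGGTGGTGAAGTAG, on the minus strand of chromosome 13 at 56189613 to 56189672 (mm9), and the array files list it for 2 of the 4 RefSeq transcripts of the gene. The difference of -1.42 (SE 0.25) had an adjusted p of 0.138 in limma without pairing and 0.033 with the replicate number as a block. An exact permutation test of this probe gave p = 0.0286 (two-sided) when pairs were ignored and 0.125 within pairs, in each case the smallest value that the samples allow, so within pairs it cannot pass 0.05. Both probes shared by all 4 transcripts were also lower, by -0.99 (SE 0.11) at 56184528 to 56184587 and -1.11 (SE 0.12) at 56205682 to 56205741. Their adjusted p was 0.054 in limma without pairing and 0.023 with it, among 24988 probes. The paired calls of all 3 probes were lost without pair 1, 2 or 3, where the limma adjusted p of the macroH2A1.1 probe was 0.131, 0.103 and 0.139 (0.0037 to 0.185 over the other settings), and without macroH2A1.1 siRNA replicate 4 all 3 passed without pairing (adjusted p = 0.029, 0.025 and 0.020). The macroH2A1.1 probe differed from the mean of the shared probes by -0.37 more, which the exact permutation test did not separate from 0 (p = 0.114 with pairs ignored and 0.25 within pairs, two-sided, n = 4). Whether other forms of macroH2A1 were lost along with macroH2A1.1 is therefore not settled. Macroh2a2, which encodes the related histone macroH2A2, read -0.11 (SE 0.10) with limma adjusted p = 0.782 without pairing and 0.376 with it. The list of both macroH2A genes holds the siRNA's target, so its calls follow the knockdown and are no separate result. It passed camera without pairing (adjusted p = 0.0047) and not with it (adjusted p = 0.054). With pairing, 4 of 11 other settings were past the threshold, with adjusted p from 0.020 to 0.56. Without pairing the call was lost with an estimated correlation, adjusted p = 0.32. The macroH2A1.1 probe differed by -0.66 in pair 4, against -1.53, -1.82 and -1.67 in pairs 1 to 3.

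**Figure D1:**
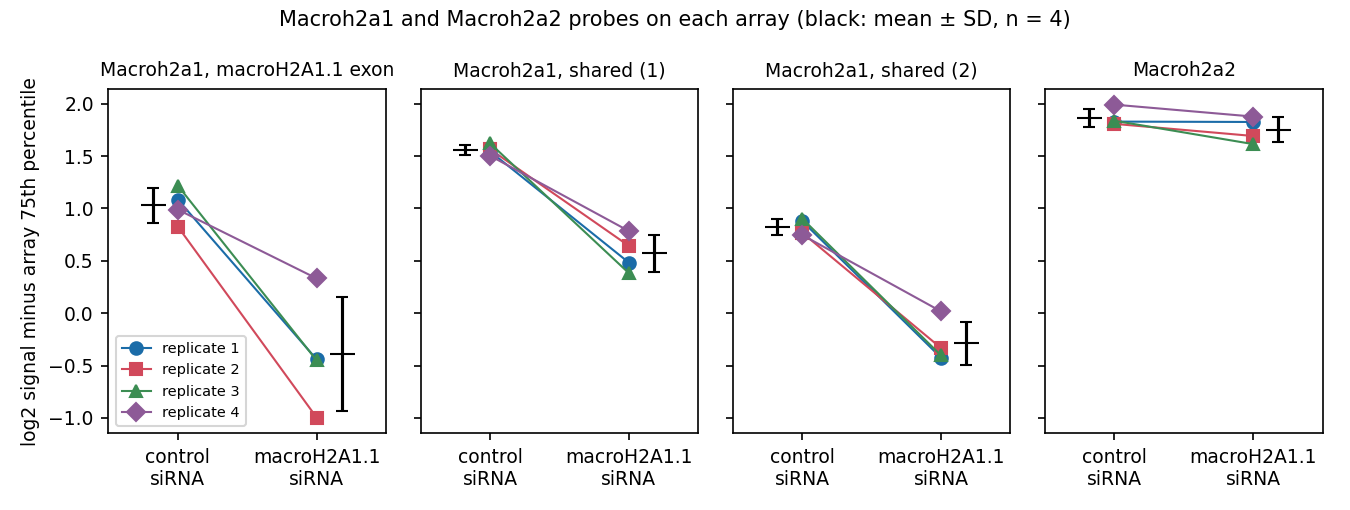
Signal of 3 Macroh2a1 probes and the Macroh2a2 probe on each array, on a log2 scale relative to the array's 75th percentile; lines join samples with the same replicate number, and black marks give the mean ± SD (n = 4). All Macroh2a1 probes are lower in every macroH2A1.1 siRNA sample, and replicate 4 shows the smallest loss on each.

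Among 13798 genes, 3 passed the threshold in the limma fit without pairing. Plin4, which coats lipid droplets, was higher with macroH2A1.1 siRNA by 1.31 (SE 0.14, adjusted p = 0.040). The chemokine gene Cxcl14 was lower by -2.29 (SE 0.20, adjusted p = 0.030), and Macroh2a1 itself was lower by -0.99 (SE 0.10, adjusted p = 0.040). With normexp background correction Cxcl14 read -0.91 (adjusted p = 0.069), and with the authors' series values -0.98 (adjusted p = 0.067), within a range of adjusted p from 0.016 to 0.069 over the settings tried. The count of 3 fell to 0 without control replicate 1 or 2 or macroH2A1.1 siRNA replicate 1, 2 or 3, to 1 without control replicate 4 and to 2 without control replicate 3, and was 11 without macroH2A1.1 siRNA replicate 4. At an unadjusted p under 0.05 there were 1666 genes, against 690 expected by chance. Samples with the same number deviated together, so the blocked values stand beside the others here. With the replicate number as a block, 564 genes were higher and 535 lower, including all 3 above, and 260 and 198 of them differed by at least 1.5-fold. This paired count rested on every part of the data: it was 0 without pair 1, 0 without pair 3, 110 without pair 2 and 537 without pair 4. It was also 0 when probes near background were kept, where 3943 genes had an unadjusted p under 0.05. Of the 1099 genes, 473 had groups that did not overlap, and 1089 of all genes did so (7.9%). Chance would give 2.86% if all arrays were exchangeable, a value that ignores the pairing. In what follows, "rose" and "fell" refer to the paired fit, and no gene other than Plin4, Cxcl14 and Macroh2a1 passed without pairing. Of 93 named genes that passed with pairing, 0 passed without pair 1, 0 without pair 3 and 0 with probes near background kept, 26 without pair 2 and 52 without pair 4, and all 93 kept their direction in each of these. In the other settings 80 to 93 of them passed, apart from the filter on all 8 arrays, where 76 were tested and 76 passed.

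Genes of the contractile apparatus moved in both directions but mostly upward. Of 55 measured sarcomere and contraction genes, 26 rose and 2 fell, and 32 and 4 did so adjusted over the list alone. The fast myosin heavy chain Myh2 rose by 2.19 (paired SE 0.16, adjusted p = 0.011), and Myoz2, a Z-disc protein, by 0.62 (adjusted p = 0.015). The slow and cardiac myosin gene Myh7 fell by 1.32 (paired SE 0.11, adjusted p = 0.012), and the calcium-binding protein gene Casq1 fell by 1.19 (adjusted p = 0.016). Myh6, a close paralog of Myh7 that its probe may share, fell by 1.23 (adjusted p = 0.012). Over the settings tried, the smallest sizes were 1.17 for Myh2 and -0.66 for Myh6. List levels (median deviation from each gene's mean) overlapped: -0.56 to 0.16 in controls, -0.17 to 0.50 with macroH2A1.1 siRNA. Replicate 2 had the lowest level in both groups, and the highest level of the cell cycle list (0.47 in control, 0.82 with macroH2A1.1 siRNA). Within pairs the macroH2A1.1 siRNA sample was higher each time, with pair medians of 0.36, 0.40, 0.34 and 0.27. The list median was 0.33, and camera gave adjusted p = 5.2e-07 without pairing and 2.9e-10 with it. This call was lost with an estimated correlation, adjusted p = 0.58 without pairing and adjusted p = 0.56 with it.

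The list of myogenic regulators, which also holds structural and membrane genes of muscle such as Lmod3 and Jph1, was higher on balance. Of its 29 measured genes, 8 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.16). Myf6, the regulator most expressed in mature fibres, rose by 2.17 (paired SE 0.32, adjusted p = 0.026), Jph1 by 0.58 (smallest size over the settings 0.325) and Lmod3 by 0.43. Myod1 rose by 0.38 (adjusted p = 0.041), while Myog read 0.06 (adjusted p = 0.685) and the embryonic myosin Myh3 read 0.12 (adjusted p = 0.383). The list had camera adjusted p = 0.0049 without pairing and 0.0021 with it, and was lost with an estimated correlation, adjusted p = 0.58 and adjusted p = 0.56. Without pairing its median moved to 0.09 (camera adjusted p = 0.090, call lost) without control replicate 2, 0.09 (call kept) without macroH2A1.1 siRNA replicate 1, and 0.24 without macroH2A1.1 siRNA replicate 2. Of 12 myotube markers, 6 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.31), among them Mylpf by 0.51, Tnnc2 by 0.43 and the creatine kinase gene Ckm by 0.41. Another of them, Myh8, rose by 0.62 although 1 of its 2 other probes had the opposite sign, and over the mean of its probes it read 0.39 and did not pass. The camera adjusted p for myotube markers was 0.0051 without pairing and 2.2e-04 with it, and was lost with an estimated correlation, adjusted p = 0.87 and adjusted p = 0.20. Without control replicate 2 or macroH2A1.1 siRNA replicate 1, the myotube call without pairing was also lost, with medians of 0.20 and 0.23 and camera adjusted p = 0.127 and 0.072.

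**Figure D2:**
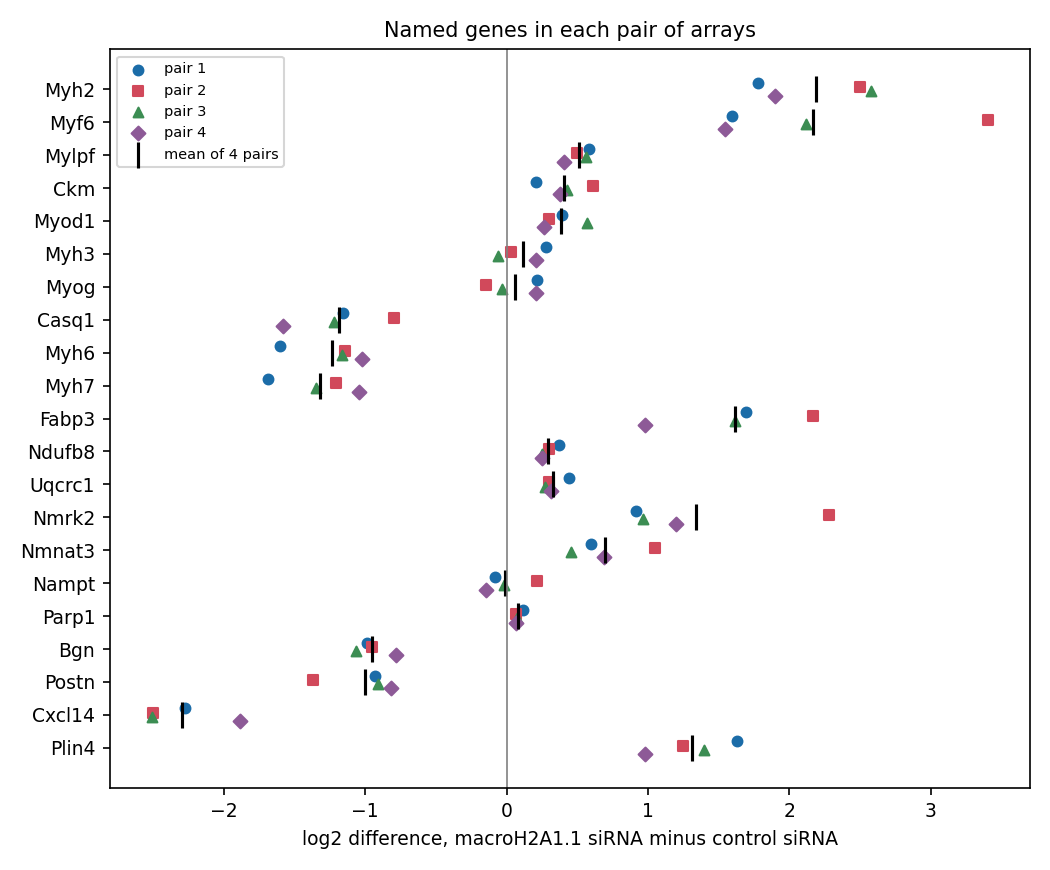
Difference between macroH2A1.1 siRNA and control siRNA in each pair of arrays for 21 named genes, on a log2 scale; symbols are pairs 1 to 4 and bars their mean. Myh2 and Myf6 are above 0 in every pair, Myh7, Myh6 and Casq1 below 0 in every pair, and Myog, Myh3 and Nampt lie on both sides.

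Nuclear genes of the respiratory chain were higher by small amounts in the median. Complex I, the NADH dehydrogenase, had a median of 0.19 over 37 genes, of which 35 read above 0. Its mean was 0.09, below the median, so low values of some members pulled it down. Of its genes 2 rose, or 8 adjusted over the list alone (Ndufv2 by 0.32 and Ndufb8 by 0.29). Complexes II to V had a median of 0.19 over 43 genes, of which 39 read above 0 and 3 rose, or 8 adjusted over the list alone (Uqcrc1 by 0.33, Cycs by 0.31 and Uqcr11 by 0.30). Camera adjusted p was 7.8e-09 and 7.3e-09 without pairing and 4.9e-07 and 1.5e-07 with it, and both calls were lost with an estimated correlation, adjusted p = 0.34 without pairing and adjusted p = 0.57 and 0.56 with it. The mitochondrial ribosome had a median of 0.11 over 75 genes, with 2 rising over all genes and 0 adjusted over the list alone. These were Mrps7 by 0.31 and Mrps25 by 0.33, although the other Mrps25 probe had the opposite sign and the mean of both, 0.08, did not pass. Its camera adjusted p was 5.9e-07 without pairing and 8.3e-06 with it, lost with an estimated correlation, adjusted p = 0.34 and adjusted p = 0.62. Fatty acid oxidation genes had a median of 0.13 over 28 genes, of which 2 rose, and 2 adjusted over the list alone: Fabp3, a fatty acid carrier of muscle, rose by 1.61 (paired SE 0.19, adjusted p = 0.017) and Acadl by 0.52. That list had camera adjusted p = 9.0e-04 without pairing and 0.0025 with it, lost with an estimated correlation, adjusted p = 0.32 and adjusted p = 0.56. For the TCA cycle the median was 0.11 over 25 genes with 0 past the test, also adjusted over the list alone. Its camera adjusted p was 0.0097 without pairing (0.053 without control replicate 1, 0.054 without replicate 2 in both groups and 0.10 with normexp) and 0.046 with it (0.111 without pair 1, where the median was 0.06 (0.0568), 0.092 without pair 2, and lost in 6 other settings with camera adjusted p up to 0.211), lost with an estimated correlation, adjusted p = 0.34 and adjusted p = 0.62. The 13 mitochondrially encoded genes had a median of 0.08 (camera adjusted p = 0.087) and 0 past the test, also adjusted over the list alone. All 13 read above 0, but the pair medians disagreed, at 0.28, -0.13, -0.02 and 0.28. Ppargc1a, a coactivator of mitochondrial genes, read 0.59 (paired SE 0.17, adjusted p = 0.093), passed in 2 of 9 other settings (adjusted p from 0.042 to 0.235) and had a smallest size of 0.3375.

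Genes that make or use NAD+ did not pass camera as lists. On the NAD synthesis list, 3 of 15 measured genes rose, and 4 adjusted over the list alone. The 3 were Nmrk2, the muscle nicotinamide riboside kinase, by 1.34 (paired SE 0.24, adjusted p = 0.038), Nmnat3 by 0.70 (adjusted p = 0.028) and Nnmt by 0.74 (adjusted p = 0.038). Nnmt methylates nicotinamide and does not itself make NAD+, so its rise is not one of synthesis. Nmnat1, the nuclear enzyme, read 0.31 with a limma adjusted p of 0.050002 that lies above the threshold and below it in 7 of 9 other settings, and Nampt read -0.01 (adjusted p = 0.950). The list had a median of 0.00 and camera adjusted p = 0.468, and the smallest sizes over the settings were 0.415 for Nmnat3, 0.40 for Nnmt and -0.255 for Parp16, an NAD consumer. Among 25 NAD consumers 1 rose and 1 fell (3 and 2 adjusted over the list alone): Art5 rose by 0.44 and Parp16 fell by 0.41, while Parp1 read 0.08 (adjusted p = 0.373), Sirt1 -0.11 over the 3 pairs that measured it (adjusted p = 0.374) and Sirt3 -0.21 (adjusted p = 0.113). Their median was 0.09 and their camera adjusted p was 0.313. In ADP-ribose binding and removal, Adprhl1 rose by 0.83, Macrod1 rose by 0.32 and Enpp1 fell by 0.81 out of 14 genes (3 higher and 1 lower adjusted over the list alone, median 0.07, camera adjusted p = 0.402). In the paired fit, camera gave adjusted p = 0.460, 0.124 and 0.251 for these 3 lists, and fry gave adjusted p = 0.0506 for NAD synthesis and 0.0395, past the threshold and upward, for NAD consumers and for ADP-ribose binding and removal.

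Interferon response genes were higher with macroH2A1.1 siRNA by the widest margin of the fixed lists, and by unequal amounts between pairs. The list median was 1.26 over 32 genes, with pair medians of 0.51, 2.32, 2.04 and 0.25. Replicate 2 of macroH2A1.1 siRNA, the array with the highest level of the list, stood apart on the first principal component of all genes (60.5 against -27.4 to 7.95 for the other arrays), and without it the median was 0.87. In the paired fit 6 rose and 0 fell, and 22 rose adjusted over the list alone (21 without pairing). Usp18 rose by 3.73 (paired SE 0.51, adjusted p = 0.023), Ifit3 by 2.88, Cxcl10 by 2.53 and Oasl1 by 2.40. Ifit3b rose by 2.91, and its signal may be shared with Ifit3. Oas1a was not well above background on any control array and rose at least 17.3-fold (limma adjusted p = 0.0495, lost in 7 other settings and on leaving out each pair in turn, with adjusted p up to 0.161), and its signal may be shared with other Oas1 genes. That bound is a mean: its pairs differed by 2.57, 7.42, 6.14 and 2.14, and without macroH2A1.1 siRNA replicate 2 it read 3.41 (log2), under the bound. Only 1 control array measured Usp18, Oasl1 or Ifit3b, and 3 measured Cxcl10. Over the settings tried, the smallest sizes were 2.365 for Oas1a, under its bound, 1.59 for Usp18, 1.27 for Cxcl10, 1.13 for Ifit3b and 0.86 for Oasl1, and with the series values Usp18 and Oasl1 did not pass. The camera adjusted p was 1.5e-15 without pairing and 3.2e-10 with it, and was lost with an estimated correlation, adjusted p = 0.34 and adjusted p = 0.57. With that gene at its bound the list median was the same, 1.26. The median was 0.81 with normexp background correction, 0.78 with the authors' series values and 0.87 over members measured on all 8 arrays. Of the macrophage markers measured, Cd68 read 1.32 (paired SE 0.37, adjusted p = 0.090, past the threshold in 1 of 9 other settings), with 2.19 as its mean over pairs 2 and 3. Over the same pairs the other markers measured read -0.17 (Itgam), -0.15 (Csf1r), -0.17 (Adgre1) and 0.12 (Cd14).

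**Figure D3:**
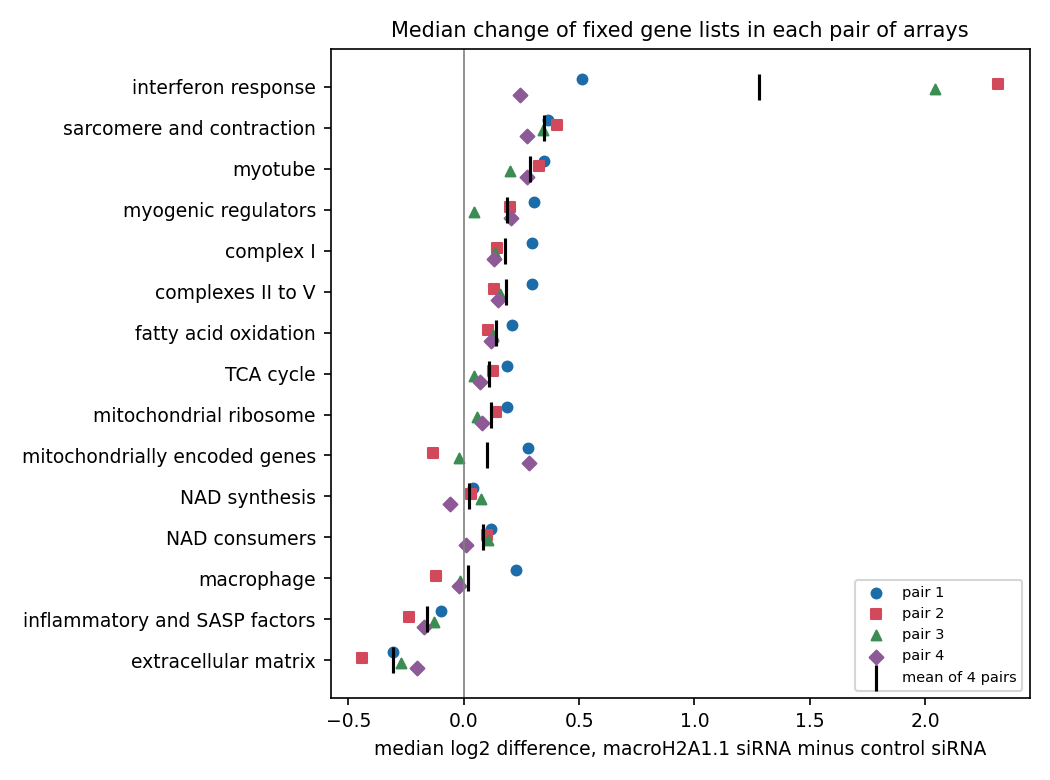
Median difference of 15 fixed gene lists between macroH2A1.1 siRNA and control siRNA in each pair of arrays, on a log2 scale; symbols are pairs 1 to 4 and bars their mean. The interferon list spreads from 0.25 to 2.32, while the extracellular matrix list lies below 0 and the complex I list above 0 in every pair.

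Extracellular matrix genes were lower. Of 46 measured, 13 fell and 1 rose (24 and 1 adjusted over the list alone), with a median of -0.32. Control replicate 4 stood apart from the other controls at a list level of -0.11, against 0.23 to 0.29 for the others, and lay within the macroH2A1.1 siRNA arrays (-0.24 to -0.10). The proteoglycan gene Bgn fell by 0.95 (paired SE 0.07, adjusted p = 0.011), the fibroblast marker Postn by 1.01, Thbs1 by 0.68 and Col18a1 by 0.63. Camera adjusted p was 2.9e-09 without pairing and 2.9e-10 with it, and was lost with an estimated correlation, adjusted p = 0.32 and adjusted p = 0.56. In adhesion and migration 3 of 39 genes fell and 0 rose (4 and 3 adjusted over the list alone), among them Cdh11 by 1.31 (smallest size over the settings -0.78) and Itgav by 0.42, with a median of -0.07 (camera adjusted p = 0.313). The list of inflammatory and SASP factors holds factors secreted by senescent cells together with inflammatory regulators that are not secreted. Of its 24 measured genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone, median -0.16). Csf1 fell by 0.54 and Tnfaip3 by 0.46, and Igfbp5 rose by 0.48. That list passed camera with pairing (adjusted p = 0.044) and not without it (adjusted p = 0.088), and was lost with an estimated correlation, adjusted p = 0.56. With pairing it passed in 5 of 11 other settings. It was lost with quantile normalization (0.063), the series values (0.053), the filter on all 8 arrays (0.061) and no filter (0.206), where the median was only -0.0131. It was also lost without pair 1, 2 or 4 (0.092, 0.067 and 0.069). Without macroH2A1.1 siRNA replicate 3 it passed without pairing (0.024) with a median of -0.10 (-0.0997).

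The largest changes of the paired fit with non-overlapping groups lay partly outside these lists. Ckmt2, the mitochondrial creatine kinase of muscle, rose by 4.19 (paired SE 0.71, adjusted p = 0.034). The glutathione transferase genes Gsta3 and Gsta2, whose probes may share signal, rose by 3.64 and 3.25, and the Gsta3 probe used was well above background on 1 control array, the gene's other probe bringing this to 2. Dusp26, Gpr37 and Reps2 were not well above background on any control array and rose at least 3.31-fold, 3.4-fold and 2.34-fold. Ecel1 rose by 2.86, Gtsf1 by 2.59, Atp9a by 2.50, Fap by 2.40 and Tceal3 by 2.38. Col8a2 fell by 3.30 (paired SE 0.31, adjusted p = 0.013), measured on 1 of the 4 macroH2A1.1 siRNA arrays. Tspan8 fell by 2.05, Cdhr1 by 1.93, Tmem171 by 1.79, Rgcc by 1.54, Il1rl1 by 1.53 and Pi16 by 1.40. Col22a1 fell by 1.37, Bach2 by 1.27, Ano1 by 1.27, Itga10 by 1.26 and Olfml3 by 1.19. Changes of dim genes were smaller with normexp background correction or the authors' series values, which leave a higher floor under dim signals. Over the settings tried, the smallest sizes were 1.665 for Gsta3, 0.59 for Dusp26, 0.54 for Gpr37, 0.45 for Reps2, 1.33 for Ecel1, 0.84 for Gtsf1, 1.03 for Fap, -1.23 for Col8a2, -0.41 for Il1rl1, -0.42 for Col22a1 and -0.30 for Bach2, so the bounds for Dusp26, Gpr37 and Reps2 were not reached in those settings. Atp9a read 1.39 over the mean of its probes.

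Other fixed lists and markers of other cell types did not pass camera without pairing, whose list values follow. Antioxidant defence held 2 rising and 4 falling genes (8 and 4 adjusted over the list alone), among them Hmox1 rising by 0.61, Gclc rising by 0.41, Txnip falling by 0.39 and Sod3 falling by 0.81, and its median was 0.10 (camera adjusted p = 0.056). Insulin and IGF signalling held Igf2 and Igfbp5 rising by 0.84 and 0.48, and Igf1 and Igfbp4 falling by 0.65 and 1.02 (4 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.809). Without pair 3 Igf1 read -0.67 on the same probe (limma adjusted p = 0.144) and -0.01 on another probe that was then the brightest, and the mean of its probes read -0.39, none past the test, and the smallest size of Igfbp4 over the settings was -0.55. Glycolysis held Slc2a4 and Ldhb rising by 0.85 and 0.61 (3 higher adjusted over the list alone, camera adjusted p = 0.688). Cholesterol and lipid synthesis held Acacb and Scd1 rising by 1.02 and 0.39 (2 higher adjusted over the list alone, camera adjusted p = 0.622), with 0.40 as the smallest size for Acacb. In the integrated and mitochondrial stress response Pycr1 fell by 0.43 (1 lower adjusted over the list alone, camera adjusted p for the list = 0.471). Cell cycle (median -0.02), p53 and cell cycle exit (0.02), atrophy and autophagy (-0.03), mitochondrial biogenesis (0.08) and housekeeping genes (0.04) held 0 genes past the test, also adjusted over the list alone, and macroH2A1 splicing regulators (0.02) held 0 over all genes and 2 higher and 1 lower adjusted over the list alone. Among undifferentiated myoblast markers (median -0.13), Cdh15 and Heyl rose by 0.39 and 0.37 and Hes1 fell by 0.36 (2 and 3 adjusted over the list alone), with -0.10 as the smallest size for Hes1, not past the test. Fibroblast markers (median -0.17) went both ways, with Postn falling by 1.01, Dpt falling by 1.09 and Fap rising by 2.40 (3 lower and 2 higher adjusted over the list alone). The adipocyte markers Fabp4 and Pparg rose by 1.41 and 0.39 out of 3 measured (2 adjusted over the list alone), with Fabp4 measured on 2 control arrays and 0.46, not past the test, as its smallest size. The neuronal marker Map2 rose by 0.41 out of 5 (1 adjusted over the list alone). Markers of osteoblasts (median -0.13), smooth muscle (-0.05), macrophages (-0.04) and endothelium (0.04) held 0 genes past the test, also adjusted over the list alone. The median and the camera direction differed in sign for glycolysis, insulin and IGF signalling, p53 and cell cycle exit, and macrophage markers.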

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

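The tests of scaling, macrophage RNA, the transfected duplex, the myotube share and the array column, all settings of the paired fit, and the limit to splits that part all pairs without pairing, were chosen after the results were seen; the splits of the arrays and the matched random lists were set beforehand. In groups of 4, a sample was singled out when its gap to the nearest other, as a share of the group's range, exceeded Dixon's 95% critical value, which chance does in about 1 of 20 groups. This happened in 14 of 207 groups for named genes, 5 of 72 for list levels and 1 of 14 for array measures, to which the principal components were added after they were seen. That 1 was macroH2A1.1 siRNA replicate 2 on the first component (60.5 against -0.94 for the nearest).

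Values here are log2 signals relative to the array's 75th percentile. Control replicate 3 stood apart for Tceal3 (-0.27 against -1.39 for the nearest), Tceal6 (0.19 against -0.82), Cdh15 (5.29 against 6.27), Bgn (5.26 against 4.67) and Enpp1 (2.60 against 1.75). Control replicate 4 did so for Macroh2a2 (1.99 against 1.84) and Tspan8 (-0.38 against 0.39), and control replicate 2 for Gpr37 (-6.46 against -4.87, both below background). Among macroH2A1.1 siRNA samples, replicate 4 stood apart for Ckmt2 (0.39 against 2.78) and replicate 2 for Myog (6.78 against 7.41). Replicate 1 did so for Gpr37 (-1.72 against -2.98) and Tmem171 (-0.99 against 0.45). Replicate 3 did so for Igf1 (0.82 against -0.46) and Igf2 (2.19 against 1.07). For list levels, given as the median deviation from each gene's mean, macroH2A1.1 siRNA replicate 2 stood apart for NAD synthesis (0.23) and replicate 3 for osteoblast (0.27) and macrophage markers (0.25). Control replicate 4 stood apart for extracellular matrix (-0.11) and control replicate 3 for neuronal markers (-0.98). Probes without a gene symbol, outside the gene comparison, held 89 calls in the paired fit among 6333 (39 higher, 50 lower) and 0 in the limma fit without pairing, where 417 had an unadjusted p under 0.05.

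Splitting the 8 arrays into 4 and 4 in other ways bears on the counts of genes. Among all 35 splits without pairing the real one gave 3 genes and the highest other 1, but since the numbers pair the samples, splits that keep pairs together are not like the real one, and differences between pairs enter them. The test on all 35 was set beforehand without this in view and is not used. Only 8 splits part all 4 pairs, too few for a share under 0.05. Among these 1, the real one, gave 3 genes without pairing and the highest other 0, and 1, again the real one, gave 564 higher and 535 lower genes with pairing and the highest other 0. Chance cannot be told apart from an effect for either count.

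Interferon genes were higher in every pair and most in pairs 2 and 3. Under other scalings of the arrays the lowest list median was 0.78, while the median of all genes stayed between -0.0038 and 0.0091. The list thus moved apart from the other genes under each scaling tried. Scalings that leave all genes so near 0 could hardly have removed the rise, so this is no strong test of scaling. All cultures were of C2C12, a myoblast line, so the design names no source of macrophage RNA. The macrophage list had a median of -0.15 over pairs 2 and 3, but its members spread by 1.03 (SD) around it. Cd68 read 2.19 there, while Itgam, the most abundant, read -0.17, Csf1r -0.15, Adgre1 -0.17 and Cd14 0.12. Itgam was already bright in control cells (mean log2 signal 4.22), so its flat value says little about a small share of macrophage RNA. Ptprc and Lyz2 were not among the genes measured, so the list by itself does not decide. A response to the transfected duplex cannot be told apart from one to the lower macroH2A1.1, since all treated samples share 1 siRNA and the list median of 1.26 belongs to both. Loss of macroH2A1.1 as the biological source remains open for the same reason. So does a loss of other macroH2A1 forms, since the probes shared by all transcripts were lower too.

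Contractile genes changed in both directions but mostly upward, as 26 of 55 sarcomere genes rose and 2 fell. If a larger share of myotubes were the whole source, members made in myotubes alone would move alike. Members also made in myoblasts would move less. Of 55 sarcomere genes, 27 (49.1%) had a 95% interval that left out the list median, 14 above and 13 below it, against about 5% for a common shift. The members were not sorted by where they are made, so this spread does not decide the question. The 2 that fell, Myh7 by 1.32 and Casq1 by 1.19, moved against such a share. A larger share of myotubes may still account for part of the shift. The loss of macroH2A1.1, a loss of other macroH2A1 forms and another effect of this siRNA all stay open, while transfection itself is shared by both groups.

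Respiratory chain genes were slightly higher in the median. The tables argue against a trend with signal level or probe GC content, since the median of 0.19 over 80 genes lay at percentile 100 of 10000 random lists matched on both, whose highest was 0.09. Under other scalings the lowest median was 0.17. All of them kept the median of all genes near 0, so this is no strong test of scaling either. The array column cannot be told apart from the group, since every even column holds macroH2A1.1 siRNA samples and the same median of 0.19 (0.1889) belongs to both. A biological source is therefore not established.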

How the results depend on the processing

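All settings of the paired fit, and leaving out replicate 2 in both groups, were chosen after the data were seen; the others were set beforehand. Values are genes, lists or log2 differences, with adjusted p in limma, and where a call changed the cause was not tested unless fewer samples or more genes tested show it. Without pairing (1 gene higher, 2 lower), normexp and the authors' series values gave 1 lower each, no filter gave 2 higher and 1 lower, the filter on all 8 arrays 3 higher, the mean of a gene's probes 3 higher and 1 lower, trended robust eBayes 2 higher, array weights 4 higher, the array row 7 higher, the array column 5 higher, and each probe on its own 0 higher and 1 lower. The replicate block gave 564 higher and 535 lower. Leaving out 1 array gave 0 to 7 higher and 0 to 4 lower, and leaving out replicate 2 in both groups gave 0 and 0, where limma had 1349 genes at an unadjusted p under 0.05.

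Of the Macroh2a1 probes, those shared by all transcripts passed without pairing at -0.91 and -0.93 with normexp, -0.89 and -0.92 (-0.8875 and -0.915) with the series values, -0.97 and -1.09 with array weights, and -0.99 and -1.11 with the filter on all 8 arrays, trended robust eBayes and the array column. With the replicate block, which is the paired fit, they passed at the same -0.99 and -1.11, and the macroH2A1.1 probe at -1.42, which it did in none of the others. Leaving out arrays gave -1.66 to -1.22 for that probe, and -1.06 to -0.92 and -1.21 to -1.07 (-1.065) for the shared ones. In the paired fit all 3 were lost with no filter (-1.42, -0.99 and -1.11, adjusted p 0.185, 0.160 and 0.163). Leaving out a pair gave -1.67 to -1.28, -1.08 (-1.075) to -0.90, and -1.24 to -1.05.

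In the paired fit, normexp gave 964 higher and 919 lower, the series values 870 and 838, trended robust eBayes 1097 and 954, array weights 1001 and 929, and no filter 0 and 0 in limma (3943 at an unadjusted p under 0.05). Leaving out a pair gave 0 to 306 higher and 0 to 231 lower, with 2761 and 2938 genes at an unadjusted p under 0.05 where the count was 0. Of the 1099 calls, 1024 were kept with normexp, 988 with the series values, 987 with quantile normalization, 870 with the mean of probes and 432 without pair 4.

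Of gene lists (8 higher, 2 lower) and marker lists (1 higher), an estimated correlation kept 0, 0 and 0 in either fit. Without pairing, fry kept 1 (fatty acid oxidation), 1 (macroH2A histones) and 0. With pairing fry called 5 higher: myogenic regulators, sarcomere and fatty acid oxidation were kept, NAD consumers and ADP-ribose binding were new, and complex I, complexes II to V, the mitochondrial ribosome, the TCA cycle and interferon response were lost. Of its lower lists, extracellular matrix was kept, macroH2A histones were new, and inflammatory factors were lost. The macroH2A histones list holds the siRNA's target, so no call of it, with or without pairing, is a separate result. Lower lists with pairing numbered 1 with quantile normalization, the series values and the filter on all 8 arrays, where inflammatory factors were lost. Leaving out arrays gave 2 to 4 lower lists and 0 to 1 higher marker lists without pairing, and leaving out a pair gave 1 to 2 lower lists.

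Directions turned only for genes that did not pass. Leaving out arrays without pairing gave -0.04 (-0.0417) to 0.23 for Myog, -0.28 to 0.19 for Nampt and -0.01 (-0.00883) to 0.18 for Parp1, with the turned end of each without control replicate 2. Leaving out a pair gave -0.08 (-0.0839) to 0.04 (0.0360) for Nampt, above 0 without pair 1 and pair 4. Of 93 named genes called with pairing, 91 stayed called with normexp (lost: Oas1a, Hes1), 88 with the series values (Oas1a, Usp18, Oasl1, Fabp4, Hes1), 91 with median centring (Oas1a, Ldhb), 85 with quantile normalization (Ckm, Oas1a, Gsta3, Ifit3b, Ndufb8, Uqcr11, Mrps7, Ldhb), 80 with the mean of probes (Oas1a, Gsta3, Ndufv2, Uqcr11, Mrps7, Mrps25, Itgav, Parp16, Igf1, Ldhb, Myh8, Map2, Hes1) and 86 with trended robust eBayes (Nmrk2, Oas1a, Ckmt2, Gsta3, Ifit3b, Ifit3, Hes1). Among named genes, 895 comparisons with a setting kept direction and side of the threshold with pairing, 424 lost the call, 14 gained one and 2 turned, against 2041, 27, 93 and 6 without pairing. Signal near background limits what the arrays measure. With the dim probes included, 23974 genes were tested and the paired calls were lost in limma. There 3943 genes had an unadjusted p under 0.05, against 3840 in the main paired fit. Whether dim signal or the larger number of genes lost the calls was not tested.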

Other observations

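The hypotheses in this part were prompted by gene names seen among the results, although each test was written down before it was run. The X-linked gene Tceal3 rose by 2.38 in the paired fit. So did 2 genes of the same family chosen after their values were seen, Tceal6 by 2.34 (adjusted p = 0.012) and Bex1 by 1.63 (adjusted p = 0.0098), and the probes of Tceal3 and Tceal6 may share signal. None of the 3 passed without pair 1 (Bex1 1.57, adjusted p = 0.055) or without pair 3. The fast myosin Myh1, likewise chosen afterwards, rose by 1.49 (adjusted p = 0.020), while Myh4 read -1.05 (adjusted p = 0.061, past the threshold in 4 of 9 other settings), and Myh1 did not pass without pair 1, 2 or 3.

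A first hypothesis was that X-linked genes rise more often, since macroH2A is known from the inactive X chromosome. Of 470 X-linked genes 23 rose (4.89%), against 4.07% elsewhere. Fisher's exact test gave adjusted p = 0.557 over the chromosomes, so the data gave no sign of it. Whether these cells carry an inactive X was not tested, so the result does not speak to silencing there.

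A second hypothesis was that neighbouring genes change together. In the order of the array files' mm9 positions, 98 neighbour pairs among 13708 genes changed in the same direction, against a mean of 43.7 in 10000 shufflings. Without neighbours that share the start of their symbol, 81 did so, against a mean of 41.7 and a highest of 64, with a permutation p = 1e-04, the smallest the shufflings can give. Shuffling ignores that muscle genes of like expression cluster and that neighbouring transcripts can overlap, so the excess is not evidence of a chromatin effect. It rests on the paired calls, which were 0 without pair 1 or pair 3.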
